A study of Mus musculus with 6 samples.

How the data were processed

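RNA samples of the mouse mesenchymal cell line C3H10T1/2 were measured, 6 in all, 3 with 50 ng/ml BMP4 during proliferation and 3 without BMP4, all collected past confluence, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

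The deposited values are linear signal intensities of biotin-labelled RNA on 1-colour arrays, made by the authors with GCOS 1.3, per the submitters' processing notes. Their scaling settings and background correction are not given in the sources used here. The 2% trimmed mean was 150 on every array, which is what a global scaling to a common target gives, so the signals were used without further scaling. Such scaling takes the total signal as equal between groups, and a shift shared by most transcripts would not be seen. The table carries no detection calls, so background was judged from the bacterial spike-in control probe sets, whose highest signal on any array was 29.1. The highest bacterial control signal was 23.5, 29.1 and 24.1 on the BMP4 arrays and 17.1, 16.6 and 21 on the control arrays. Median bacterial control signals overlapped, at 8.4, 7.8 and 4.1 against 5.3, 3.6 and 4.7. Of the probe sets other than controls, 59%, 57% and 56% lay above 29.1 on the BMP4 arrays. On the control arrays 55.7%, 54.4% and 54.9% did. Small rises of dim genes cannot be told apart from this difference. Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation used, 932 had several and 9211 were unnamed here. No gene was named from a probe set with several symbols. Gene identifiers of 34754 probe sets matched the GRCm38.p6 gene table, which changed 0 symbols. The table was used for names only, and no coordinates are given because the files name no genome build.

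The 64 control probe sets were left out, 16 was added to each signal, and log2 values were taken. Probe sets were kept when their mean log2 value over all 6 arrays was above the 40th percentile, which corresponded to a signal of 23.5 and left 27022. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. Fold changes are on the log2(signal + 16) scale, which understates the change of genes with low signal. Errors of signals are SD over 3 arrays, and errors of log2 changes are moderated SE from limma. A 2-fold change means an absolute log2 change of at least 1.

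A gene was represented by its kept probe set with 1 symbol and the highest mean. Before the data were examined, 38 lists with 692 different genes were fixed from general knowledge, of which 549 genes were measured after the filter. They cover BMP response and signalling, adipocyte commitment, transcription factors, mature and brown adipocytes, lipid and sterol synthesis, osteoblasts, chondrocytes, muscle, contractile and TGF-beta genes, matrix, growth factors, Wnt, Notch and Hedgehog, cell cycle, DNA methylation, interferon and cytokines, stress, metabolism, patterning factors and markers of 4 other cell types. The 37 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Calls of members use the adjustment over all probe sets and, separately, one over the list alone. Camera compares a list with the other genes and does not work on the mean log2 change, so its direction can differ from the sign of the list's own mean.

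The genes named were chosen by a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, up to 3 called members per list by size of change, or the member with the smallest p where none was called, and 22 genes fixed by name. A fixed name had no named probe set here and is not reported here. Further list members are named after their values were seen, where the text says so, or, among adipocyte progenitor, adipogenic and mature adipocyte genes, to complete the genes that fell. Of 70 other kept probe sets of the 106 called named genes, 68 moved the same way, 47 of them past the test, and 0 passed in the opposite direction.

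The test was first run on simulated values for the comparison of BMP4 with control, built on the 27022 real probe set means with 50 probe sets changed at each size. It recovered 30% of those changed 1.5-fold, 62% of those changed 2-fold, 92% of those changed 3-fold and 94% of those changed 4-fold, with 3 false calls and 0 calls when nothing was changed. Only 200 probe sets were changed in the simulation, against 2464 called in the real data. The adjustment was therefore stricter in the simulation, and these shares do not measure recovery in the real comparison. Alternatives tried were other pseudocounts, no filter and a filter at the 60th percentile, quantile normalization, median centring, cyclic loess, eBayes without the trend, robust eBayes, array weights, a replicate block, leaving out each array, and the mean of all probe sets of a gene. Figures were drawn with matplotlib 3.10.9.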

Results

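The series addressed which genes respond to BMP4, a secreted ligand of the bone morphogenetic protein family, when C3H10T1/2 cells commit to the adipocyte lineage. C3H10T1/2 is a mouse mesenchymal cell line that can form adipocytes, cartilage, bone and muscle cells in culture. Cells received 50 ng/ml BMP4 while they proliferated, or no BMP4, and total RNA was taken after both had grown past confluence. Each group held 3 samples, and each sample was hybridised to 1 single-colour array of 45101 probe sets. The 2% trimmed mean signal was 150 on each of the 6 arrays. Median signals were 42.6, 38.9 and 37.6 on the BMP4 arrays and 37.3, 35.2 and 35.9 on the control arrays. The ratio of 3' to 5' signal for Gapdh was 0.736, 0.71 and 0.737 with BMP4 and 0.688, 0.736 and 0.688 without it. The same ratio for beta-actin was 1.18, 1.17 and 1.19 with BMP4 and 1.27, 1.19 and 1.16 without it. Correlations of log2 signals across probe sets were 0.9781 to 0.9833 between BMP4 arrays, 0.9844 to 0.9861 between control arrays and 0.9651 to 0.9745 across the groups. With 3 arrays per group, the number of arrays limits the precision of every value.

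BMP4-treated cells differed from control cells at 2464 of the 27022 probe sets tested with limma at an adjusted p of 0.05, of which 1136 were higher and 1328 were lower. At 321 of these the change was at least 2-fold, with 145 higher and 176 lower. Counted with 1 probe set per gene, 1386 of 12966 genes changed, 652 upward and 734 downward. The 3 arrays of one group lay wholly above the 3 of the other at 2460 of the changed probe sets. Over all probe sets tested this held for 7619 (28.2%), against 10% by chance. Of 37 gene lists tested with camera, 6 were shifted upward and 5 downward at the preset correlation of 0.01. With an estimated correlation 0 lists passed (limma camera, lowest adjusted p = 0.13, with 6 lists at an unadjusted p under 0.05), and fry called 15. Camera at the preset correlation called up to 10 lists when the 6 arrays were divided in other ways, against 11 for the real groups. Every other division put arrays of both groups on both sides. It thus kept part of the difference between the groups, so these counts do not give a rate of false calls. Where each array was centred on its median, 2522 probe sets passed and 25.1% of them were higher, against 46.1% as deposited. Leaving out control replicate 2 gave 1622 changed probe sets, and a fit without the intensity trend gave 1422.

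**Figure D1:**
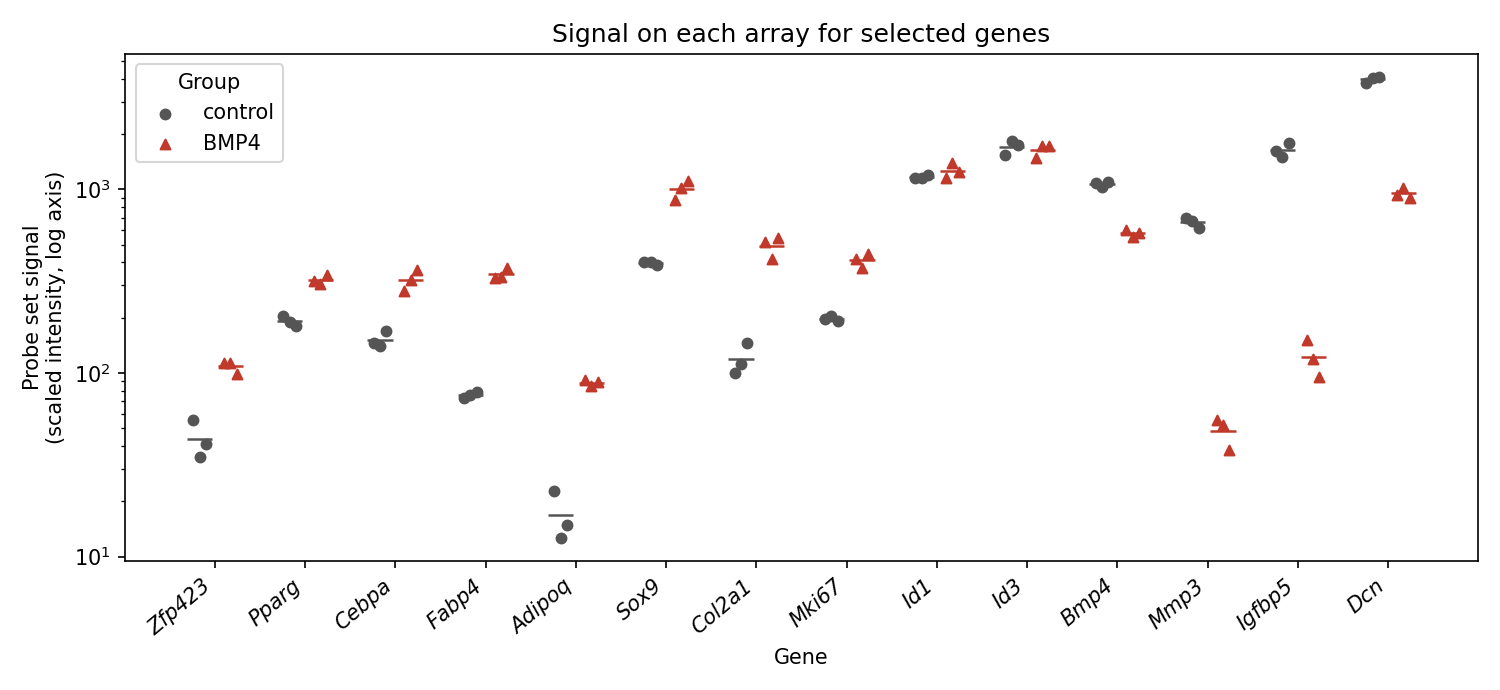
Signal of 14 genes on each array, on a logarithmic axis of scaled intensity, with control arrays as circles, BMP4 arrays as triangles and a bar at each group mean. The groups do not overlap for Zfp423, Pparg, Cebpa, Fabp4, Adipoq, Sox9, Col2a1 and Mki67, which were higher with BMP4, or for Bmp4, Mmp3, Igfbp5 and Dcn, which were lower, and they overlap for Id1 and Id3.

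The largest rises included secreted proteins, an enzyme of sulfate metabolism, and genes known from fat, cartilage and epithelia. Wfdc18, a small secreted protein with a whey acidic protein domain, rose from a signal of 149 ± 5.17 to 1213 ± 126 (SD, n = 3), a log2 change of 2.89 ± 0.08 (SE, limma adjusted p = 4.73e-08). Papss2, which makes the sulfate donor used in proteoglycan synthesis, rose from 103 ± 13.4 to 856 ± 268, a log2 change of 2.84 ± 0.17 (adjusted p = 3.43e-06), while 2 further probe sets gave 2.08 and 1.62. Penk, the precursor of the enkephalin opioid peptides, rose 5.29-fold, and Il1rn, the antagonist of the interleukin-1 receptor, rose 4.65-fold to a signal of 4621. Fabp4, the fatty acid carrier of adipocytes, rose 3.91-fold, against 4.43-fold and 1.49-fold (adjusted p = 0.0733) on 2 dimmer probe sets. Col2a1, the main collagen of cartilage, rose 3.79-fold, and Cd24a, a surface glycoprotein, rose 3.77-fold. The keratin Krt15 rose by a log2 change of 2.32, the secreted Wnt antagonist Frzb by 1.98 (0.88 on another probe set, adjusted p = 0.0308) and the tight junction protein Cldn19 by 1.90. In control cells these 3 genes had mean signals of 5.10, 5.97 and 10.7, under the highest bacterial spike-in control signal of 29.1, so the signal they rose from was not above background.

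The largest falls included receptors, secreted regulators, proteases and enzymes. Agtr2, the type 2 receptor for angiotensin II, fell from a signal of 722 ± 61.3 to 37.8 ± 14.6 (SD, n = 3), a log2 change of -3.81 ± 0.16 (SE, limma adjusted p = 3.62e-07). Igfbp5, which binds insulin-like growth factors, fell from 1636 ± 141 to 122 ± 28.1, a log2 change of -3.60 ± 0.13 (adjusted p = 9.39e-08). A dimmer Igfbp5 probe set, with signals of 451 and 167, gave -1.44 (adjusted p = 0.00922), so the size of this fall depends on the probe set. Mmp3, a matrix metalloproteinase of broad specificity, fell from 665 ± 40.5 to 48.5 ± 9.37, a log2 change of -3.41 ± 0.12 (adjusted p = 9.39e-08). The keratan sulfate proteoglycan Kera changed by -2.85 and the collagenase Mmp13 by -2.74 on the log2 scale. Both were at or under the bacterial control signal on every BMP4 array. Gfra1, the co-receptor for glial cell line-derived neurotrophic factor, changed by -2.47, and the metalloreductase Steap4 by -2.46. The protease inhibitor Serpinb1a changed by -2.36, the aminopeptidase Enpep by -2.19 and the cytochrome P450 Cyp2f2 by -2.13.

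Direct targets of BMP signalling were mostly not past the test at this time, while the cells' own Bmp4 transcript fell. Bmp4 went from 1069 ± 31.4 to 577 ± 26.6 (SD, n = 3), a log2 change of -0.87 ± 0.07 (SE, limma adjusted p = 1.51e-05). Id1 and Id3, inhibitors of helix-loop-helix factors and early BMP targets, had log2 values of 0.10 (95% interval -0.07 to 0.27, adjusted p = 0.477) and -0.05 (-0.24 to 0.14, adjusted p = 0.772). The inhibitory Smads gave 0.41 for Smad6 (adjusted p = 0.0556) and -0.01 for Smad7 (95% interval -0.29 to 0.28, adjusted p = 0.977). Among 19 measured BMP-Smad response genes 1 rose, the decoy receptor Bambi (log2 0.53), while Id2 (-0.40) and Fst, which encodes the activin and BMP antagonist follistatin (-0.98), fell. Another Fst probe set, with signals of 386 without and 273 with BMP4, gave -0.48 (limma adjusted p = 0.00552). Adjusted over the list alone, 3 rose and 2 fell, and the list as a whole was not past the test (camera adjusted p = 0.635). Of 16 measured BMP ligands, receptors and signal carriers 0 rose and 3 fell, namely Bmp4, Rgma, a BMP co-receptor (-0.69), and Tgfbr3, the co-receptor betaglycan (-0.71); adjusted over the list alone, 4 fell. That list shifted downward (camera adjusted p = 0.00321; adjusted p = 0.278 with an estimated correlation), and the receptor Bmpr1a gave -0.05 (adjusted p = 0.663). The call of Id2 was lost without BMP4 replicate 1 (adjusted p = 0.0718), control replicate 1 (0.074) or control replicate 2 (0.0589), which left Fst as the 1 lower response gene; there was also 1 lower gene without the filter or the intensity trend. The list had 2 higher genes without BMP4 replicate 1 or control replicate 3, and with a pseudocount of 64, quantile normalization, cyclic loess, robust eBayes, array weights or a replicate block. It had 3 with a filter at the 60th percentile.

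The adipocyte regulators Zfp423, Pparg and Cebpa and some genes of mature adipocytes were higher with BMP4, while the progenitor and adipogenic factor lists moved both ways. Zfp423, a zinc finger factor of preadipocyte commitment, rose from 43.8 ± 10.5 to 109 ± 8.60 (SD, n = 3), a log2 change of 1.08 ± 0.16 (SE, limma adjusted p = 0.00162). Pparg and Cebpa, which together drive terminal adipogenesis, rose by 0.70 ± 0.09 (adjusted p = 0.000402) and 1.01 ± 0.11 (adjusted p = 0.000188). Of 13 measured progenitor and commitment genes 4 rose, including the preadipocyte factor Dlk1 (1.26) and Cd24a (1.92). In the same list 3 fell, namely Ebf1 (-0.64), Pdgfra, a receptor marking mesenchymal progenitors (-0.90), and the matricellular gene Ccn5 (-1.18). Adjusted over the list alone the numbers were 5 and 4, and its median was -0.06, its mean 0.11 and its camera direction downward (adjusted p = 0.906). The lysyl oxidase gene Lox gave 0.34 (adjusted p = 0.1). Of 16 adipogenic transcription factors 4 rose and 2 fell, the latter Klf4 (-0.46) and Klf6 (-0.35), or 5 and 7 adjusted over the list alone. Cebpb and Cebpd, which act early in adipogenesis, gave -0.28 (adjusted p = 0.0744) and -0.25 (adjusted p = 0.082), with another Cebpd probe set at 0.22 (adjusted p = 0.297). The median of this list was -0.12, its mean 0.03 and its camera direction downward (adjusted p = 0.633), and with arrays centred on their medians 3 rose and 6 fell, with cyclic loess 4 and 4, and without the intensity trend 2 and 1.

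Of 14 measured genes of mature adipocytes 4 rose and 1 fell, or 5 and 2 adjusted over the list alone. Fabp4 had a signal of 76.2 ± 2.90 without and 345 ± 24.4 with BMP4 (SD, n = 3). Adipoq, the hormone adiponectin, rose by 1.69 ± 0.18 (SE, limma adjusted p = 0.000146) and the carbonic anhydrase Car3 by 1.05, both from control signals at background level. Plin2, a coat protein of lipid droplets, rose by 0.99, and is named after its value was seen, while the lipoprotein lipase gene Lpl fell (-0.63). The list shifted upward (camera adjusted p = 0.0163; adjusted p = 0.26 with an estimated correlation), a call lost when probe sets under the 60th percentile were left out (adjusted p = 0.175). Without BMP4 replicate 3, control replicate 1 or control replicate 3 no member was called lower, and with median centring 2 were. Of 7 measured brown adipocyte genes 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.633), and the smallest p belonged to the brown fat regulator Prdm16 (log2 0.47, limma adjusted p = 0.127).

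Genes of sterol synthesis and some of fatty acid synthesis were higher with BMP4. Of 16 measured cholesterol synthesis genes 11 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 6.86e-10; adjusted p = 0.13 with an estimated correlation). The sterol methyl oxidase Msmo1 rose from 1270 ± 204 to 2211 ± 163 (SD, n = 3), a log2 change of 0.80 ± 0.11 (SE, limma adjusted p = 0.000957). Fdps, which makes farnesyl diphosphate, rose by 0.79, and the squalene epoxidase Sqle by 0.62. Of 17 fatty acid and triglyceride synthesis genes 7 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.000535; adjusted p = 0.26 with an estimated correlation). Acaca, the enzyme of the committed step of fatty acid synthesis, rose by 0.56 ± 0.07 (adjusted p = 0.000348), and the desaturases Scd1 and Fads2 rose by 0.57 and 0.47. Without the intensity trend Scd1 (adjusted p = 0.059) and Fads2 (0.0723) were not past the test, nor was Fads2 with median centring (0.0752) or on another probe set (log2 0.18, adjusted p = 0.204). The member that fell was Gpam, which starts triglyceride synthesis (-0.26), named after its value was seen. The number of higher sterol genes was 7 without BMP4 replicate 3 or control replicate 1, and 5 with median centring or without the intensity trend. The number of higher fatty acid genes was 4 without BMP4 replicate 1, BMP4 replicate 3 or control replicate 2, was 2 with median centring and 1 without the trend, and Gpam was not called when any 1 array was left out.

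Of 14 measured chondrocyte genes 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 1.05e-06; adjusted p = 0.13 with an estimated correlation). Col2a1 went from 119 ± 23.4 to 494 ± 67.6 (SD, n = 3), a log2 change of 1.92 ± 0.13 (SE, limma adjusted p = 8.6e-06). Sox9, the transcription factor that directs cartilage formation, went from 398 ± 10.8 to 1003 ± 120, a log2 change of 1.29 ± 0.09 (adjusted p = 6.52e-06). Another Sox9 probe set gave 1.26 (adjusted p = 0.000208), and a dimmer one, with signals of 26.5 and 29.4, gave -0.11 (adjusted p = 0.812). Of 8 measured osteoblast genes 2 rose and 2 fell, also adjusted over the list alone. The endopeptidase Phex, which acts in bone mineralisation, fell by 1.16 on the log2 scale. A dimmer Phex probe set gave -0.70 (limma adjusted p = 0.00339), and the proteoglycan Omd fell by 0.64. The receptor gene Tnfrsf11b rose by 0.52 (limma adjusted p = 0.0423), and by 0.66 on a dimmer probe set (adjusted p = 0.0354). The pyrophosphate transporter Ank rose by 0.37, and is named after its value was seen. The list had a median of 0.02 and a mean of -0.09, and camera pointed downward (adjusted p = 0.673). Its number of higher genes was 1 without any of the 3 BMP4 replicates, control replicate 2 or control replicate 3, and 0 with median centring.

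The muscle lists were not past camera as groups. By fry skeletal muscle genes passed (adjusted p = 0.0369), while smooth muscle and contractile genes did not (0.763). Of 9 measured skeletal muscle genes 1 rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.327), and the myogenic factor Myod1 was near background at 28.6 ± 13.5 and 28.7 ± 4.06 (SD, n = 3; log2 -0.04, limma adjusted p = 0.943). Of 15 smooth muscle and contractile genes 3 rose and 2 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.633). Tropomyosin 1, Tpm1, fell by 0.42 (adjusted p = 0.0099) and the myosin light chain Myl9 fell by 0.39, and Tpm1 was not past the test without the intensity trend (adjusted p = 0.0626). The actin gene Acta2 rose by 0.37 (limma adjusted p = 0.0329), a call lost with median centring (adjusted p = 0.152). Of 15 TGF-beta and YAP response genes 4 rose and 3 fell, or 4 and 6 adjusted over the list alone. Ccn2, a matricellular target of both pathways, rose by 1.29 ± 0.11 (SE, adjusted p = 3.86e-05), and the ligand Tgfb2 rose by 0.93. This list had a median of -0.09, a mean of 0.06 and a downward camera direction (adjusted p = 0.633). The number of higher contractile genes was 1 without BMP4 replicate 1 or control replicate 1 and 0 with median centring, while the number of lower ones was 3 without control replicate 1 or 2, with quantile normalization and with cyclic loess, and 4 with median centring. Without the intensity trend 0 rose and 1 fell. The only skeletal muscle call was lost with median centring and without any 1 array except BMP4 replicate 1. With median centring 2 TGF-beta and YAP response genes were higher and 6 were lower.

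Matrix genes moved in both directions. Dcn, a small leucine-rich proteoglycan that binds collagen, fell from 3977 ± 143 to 954 ± 63.3 (SD, n = 3), a log2 change of -2.04 ± 0.07 (SE, limma adjusted p = 9.39e-08). Among 19 small proteoglycans and matricellular genes 4 rose and 6 fell, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.289, fry adjusted p = 0.00837). Those that fell included Spon2 (-1.20, but -0.14 with a limma adjusted p of 0.681 on a dimmer probe set) and the collagen-binding Lum (-0.89). Of 26 fibrillar and basement membrane genes 3 rose and 7 fell, also adjusted over the list alone. Within it Col15a1 rose by 1.62 ± 0.11 (adjusted p = 6.81e-06) and Col18a1 changed by -1.89 ± 0.08 (adjusted p = 4.65e-07), both being basement membrane collagens. That list had a median of 0.05, a mean of -0.03 and a downward camera direction (adjusted p = 0.633). Of 18 collagen modification and crosslinking genes 2 rose, the prolyl hydroxylase P3h2 (1.31) and the lysyl oxidase Loxl4 (0.85), and 2 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.633). The number of higher proteoglycan genes was 2 without BMP4 replicate 1 or 2, 1 without control replicate 3 and 0 with median centring. The number of lower collagen modification genes was 1 without BMP4 replicate 1, BMP4 replicate 2, control replicate 1 or control replicate 3.

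Several matrix proteases were lower with BMP4. Of 18 measured proteases and inhibitors 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.372 with an estimated correlation). Besides Mmp3 and Mmp13, the aggrecan-cleaving Adamts5 fell from 2236 to 961, a log2 change of -1.21 ± 0.07 (SE, n = 3, limma adjusted p = 2.13e-06). The other members that fell, named after their values were seen, were Adamts1 (-1.06) and Plat, the tissue plasminogen activator (-0.76). Timp3, an inhibitor of metalloproteinases, rose by 0.54, and is named after its value was seen.

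Igfbp5, Igfbp3 and Igfbp4, which bind insulin-like growth factors, changed by -3.60, -2.06 and -1.45 on the log2 scale. Igfbp3 went from 347 to 71.2 (limma adjusted p = 7.2e-07) and Igfbp4 from 2344 to 849 (adjusted p = 7.2e-07, n = 3). Of 6 measured binding proteins of this family, counted after their values were seen, these 3 fell and 0 rose. Of the 27 genes of the insulin-like and fibroblast growth factor list 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.23 with an estimated correlation). The gene that rose, named after its value was seen, was Fgfr2, a fibroblast growth factor receptor (1.32 ± 0.09 SE, adjusted p = 5.96e-06).

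Individual members of the Wnt, Notch and Hedgehog pathways moved in both directions. Of 16 Wnt ligands and secreted inhibitors 1 rose, Frzb, and 2 fell, the inhibitor Dkk2 (log2 -1.29 ± 0.11 SE, n = 3, limma adjusted p = 3.91e-05) and Sfrp2 (-0.73), or 2 and 3 adjusted over the list alone. Of 9 Wnt pathway response genes 0 rose and 2 fell, or 1 and 2 adjusted over the list alone. Those that fell were Znrf3 (-0.41, limma adjusted p = 0.0186) and the cyclin gene Ccnd1 (-0.315, adjusted p = 0.04). In the Notch list of 15 genes 2 rose and 2 fell, also adjusted over the list alone, with the target Hes1 at 1.04 (adjusted p = 0.00306) and the receptor Notch3 at -1.20 (adjusted p = 1.72e-06), or -0.55 on a dimmer probe set (adjusted p = 0.133). Among 8 Hedgehog pathway genes 1 rose, the co-receptor Boc (0.46), and 2 fell, including the co-receptor Cdon (-0.42), also adjusted over the list alone. Camera adjusted p-values were 0.633, 0.782, 0.673 and 0.633 for these 4 lists in turn. Their medians and means were -0.04 and 0.02 for Wnt ligands, 0.005 and 0.06 for Wnt responses, 0.12 and 0.09 for Notch and -0.08 and 0.001 for Hedgehog, with camera pointing downward in all but Notch. Frzb fell under the signal filter when any 1 BMP4 replicate was left out, and Hedgehog had 1 lower gene without any 1 array and 0 without the intensity trend, where Cdon had an adjusted p of 0.0523. Wnt response genes had 1 lower member without BMP4 replicate 1 and 0 without BMP4 replicate 2 or any 1 control replicate, and it had 1 higher member without BMP4 replicate 3. Notch had 1 higher member with median centring, and without BMP4 replicate 2, BMP4 replicate 3, control replicate 1 or control replicate 2. It had 1 lower member without BMP4 replicate 1, BMP4 replicate 2, control replicate 1 or control replicate 2.

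Most measured genes of mitosis and DNA replication were higher in the BMP4-treated cultures after confluence. The cyclin gene Ccnd1, listed with the Wnt responses, was lower. Of 22 measured mitosis genes 18 rose and 0 fell, or 20 and 0 adjusted over the list alone (camera adjusted p = 3.81e-18; adjusted p = 0.13 with an estimated correlation). The proliferation marker Mki67 went from 198 ± 5.65 to 412 ± 35.2 (SD, n = 3), a 2-fold rise (log2 SE 0.08, limma adjusted p = 3.15e-05). The mitotic kinase Plk1 rose by 1.21 ± 0.19 (adjusted p = 0.00219) and Cdc20, an activator of the anaphase-promoting complex, by 1.08 ± 0.09 (adjusted p = 2.22e-05). Of 24 DNA replication genes 17 rose and 0 fell, or 21 and 0 adjusted over the list alone (camera adjusted p = 5.75e-15; adjusted p = 0.13 with an estimated correlation). Among them the thymidine kinase Tk1 rose by 1.19 and the ribonucleotide reductase subunit Rrm2 by 1.17. Of 15 growth arrest genes 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.482), and Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 0.66 ± 0.08 (adjusted p = 0.000565). Of 9 DNA methylation genes 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.633), with the maintenance methyltransferase Dnmt1 at 0.20 (adjusted p = 0.0973). Without any 1 array except BMP4 replicate 1 the growth arrest list had 0 lower genes, and with median centring it had 2 higher ones.

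Of 14 measured cytokine and acute-phase genes 8 fell and 0 rose with BMP4, or 8 and 2 adjusted over the list alone, and 2 rose with quantile normalization and 1 with cyclic loess (camera adjusted p = 0.000345; adjusted p = 0.278 with an estimated correlation). Il6, an inflammatory cytokine, went from 126 to 19.2, at or under background on the BMP4 arrays, and the neutrophil chemokine Cxcl5 changed by -1.79 ± 0.15 (SE, n = 3, limma adjusted p = 3.54e-05). The complement factor Cfb changed by -0.92 (adjusted p = 0.0071). Of 18 interferon response genes 0 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.272). The number of lower interferon genes was 1 without BMP4 replicate 2, BMP4 replicate 3 or control replicate 3, and 0 without control replicate 1 or 2.

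The stress and energy lists were not past camera as groups, while single members changed. By fry the unfolded protein response list (adjusted p = 0.0168) and the glycolysis and hypoxia list (0.0133) passed. The heat shock, antioxidant and oxidative phosphorylation lists did not. Of 15 unfolded protein response genes 4 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.078), led by Chac1, a glutathione-degrading enzyme (log2 1.05 ± 0.11 SE, n = 3, limma adjusted p = 0.000129), and the asparagine synthetase Asns (0.97). Of 13 heat shock genes 2 rose and 0 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.534), among them the small heat shock protein Cryab (0.80 ± 0.11, adjusted p = 0.00101). Of 14 glycolysis and hypoxia genes 4 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.076), the fall being in Adm, the vasodilator peptide adrenomedullin (-2.00 ± 0.12, adjusted p = 3.43e-06). Of 14 Nrf2 antioxidant genes 3 rose and 4 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.695), with the quinone reductase Nqo1 at 0.80 and Gclc, a subunit of the enzyme that starts glutathione synthesis, at -1.20. Of 20 oxidative phosphorylation genes 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.633), with the smallest p for Cycs, cytochrome c (0.22, adjusted p = 0.127). The number of higher glycolysis genes was 1 without BMP4 replicate 2 or 3, 2 without any 1 control replicate or with a replicate block, 1 without the filter, and 0 with median centring or without the intensity trend, and that of unfolded protein response genes was 2 without BMP4 replicate 1, BMP4 replicate 2 or control replicate 2, and with median centring. The unfolded protein response list had 1 lower gene without BMP4 replicate 3 or control replicate 1, and with quantile, median or cyclic loess normalization. Heat shock genes had 1 higher member without any 1 control replicate, and 2 lower members with median or cyclic loess normalization and 1 with quantile normalization. With quantile normalization 1 oxidative phosphorylation gene rose. Without BMP4 replicate 1, control replicate 2 or control replicate 3 the antioxidant list had 2 lower genes.

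Among transcription factors that pattern mesenchyme more fell than rose. Of 15 measured members 6 fell and 2 rose, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.23 with an estimated correlation). Osr2, a zinc finger factor of limb and palate development, went from 327 to 105, a log2 change of -1.52 ± 0.13 (SE, n = 3, limma adjusted p = 3.91e-05), and its relative Osr1 changed by -0.51. The forkhead factor Foxc2 rose by 0.53 (adjusted p = 0.00105). The list was not past the test without a filter on low signals (adjusted p = 0.063). It had 3 lower genes without BMP4 replicate 1, control replicate 1 or control replicate 2, without the filter or the intensity trend and with a replicate block, and 1 higher gene without BMP4 replicate 1, BMP4 replicate 2 or control replicate 2, without the filter or the trend, and with median centring.

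Single mural and endothelial markers passed the limma test, where 1386 of all 12966 genes did. Lists of this size do not show whether markers of other cell types were called less often than other genes. Of 7 endothelial markers 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.5). Of 7 macrophage and blood markers 0 rose and 0 fell (camera adjusted p = 0.633), and of 5 epithelial markers 0 rose and 0 fell (camera adjusted p = 0.731), each also adjusted over the list alone. The smallest p in these belonged to the lysozyme Lyz2 (signals 53.5 and 29.2, limma adjusted p = 0.0853) and the keratin Krt14 (29.3 and 19.4, adjusted p = 0.37). Of 4 mural markers, too few for camera, 0 rose and 1 fell, the aminopeptidase Anpep (log2 -1.10 ± 0.10 SE, n = 3, adjusted p = 6.2e-05), also adjusted over the list alone. The endothelial call was lost without BMP4 replicate 3, control replicate 1 or control replicate 3.

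**Figure D2:**
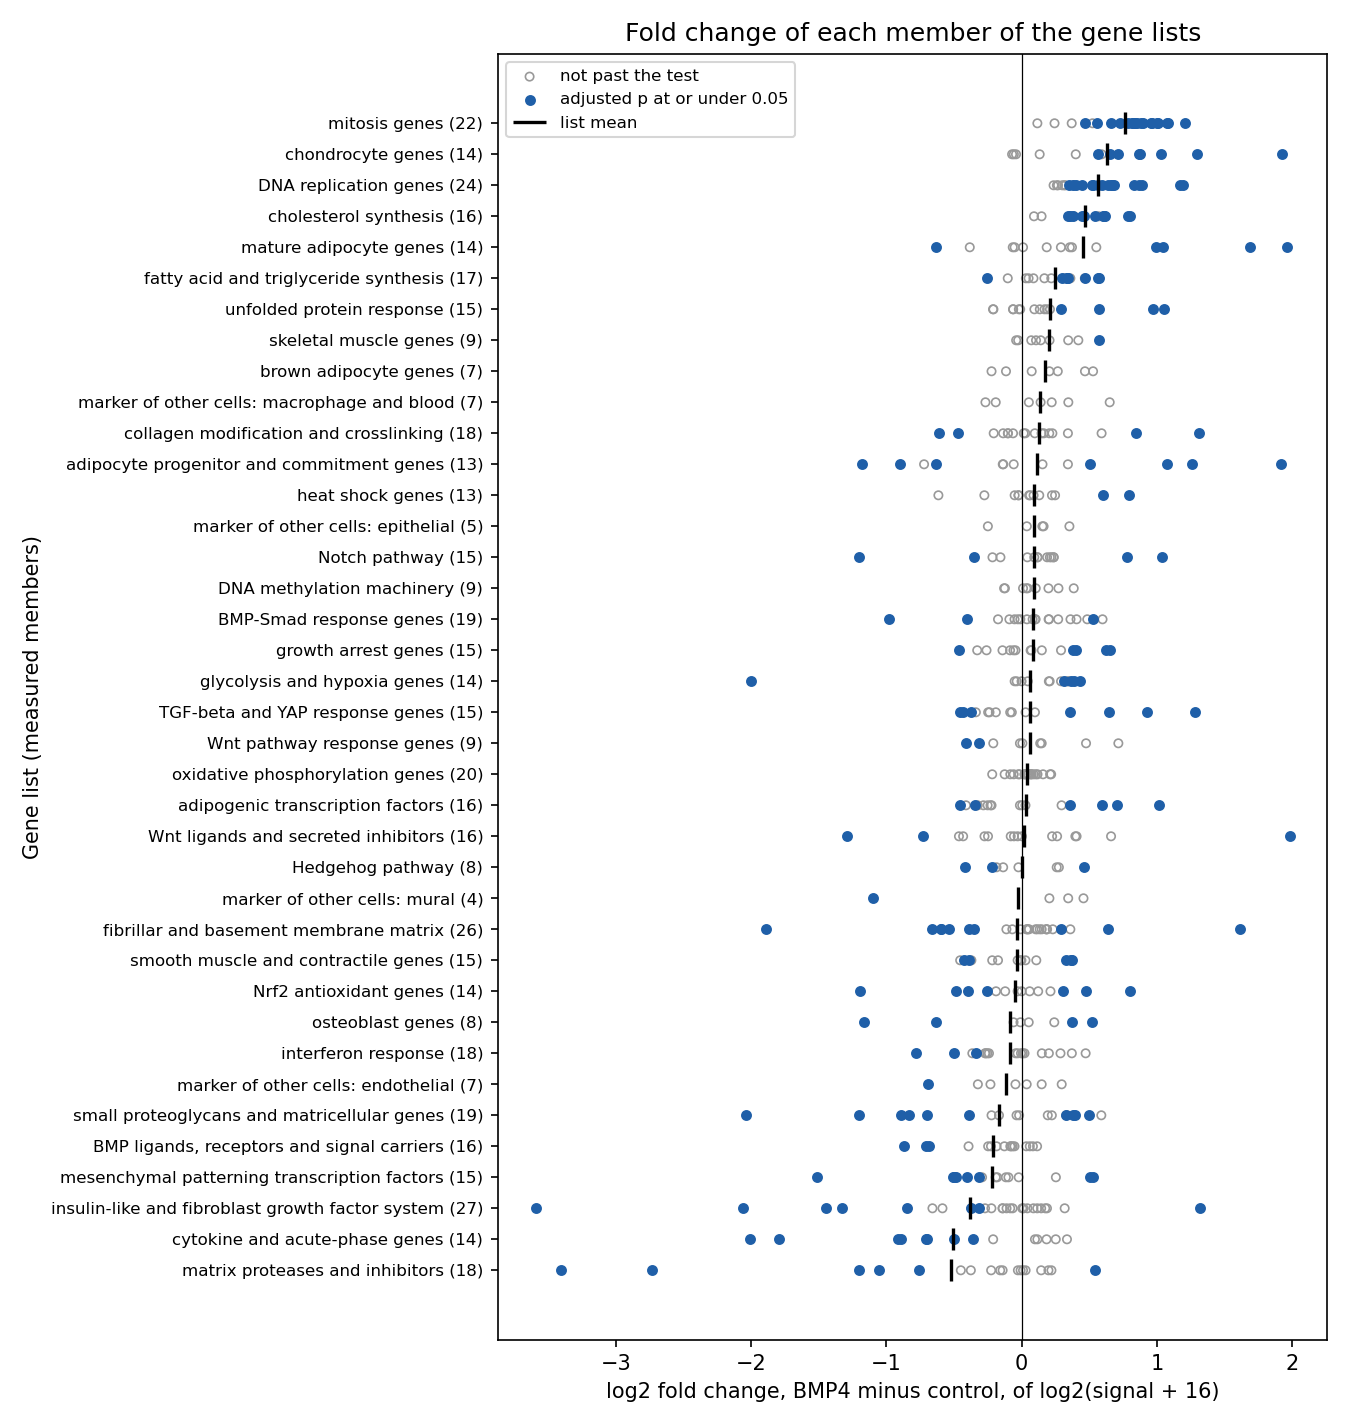
Log2 fold change of each measured member of the 38 gene lists, with filled points past the limma test, open points not past it, a bar at each list mean and the number of measured members in parentheses. Mitosis genes have the highest mean (0.77) and matrix proteases the lowest (-0.52).

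Of the 106 named genes that passed, 21 lost the call when at least 1 array was left out. Leaving out an array also weakens the test, with 1622 to 1996 probe sets called against 2464. Such a loss can therefore mean a value close to the threshold and need not come from that array. Gli3, Stat2 and Tgfb1 were not past the test without any 1 of the 6 arrays (limma adjusted p up to 0.165). The calls of Gadd45g, Iigp1 and Mef2c were lost without BMP4 replicate 2 or 3 or any 1 control replicate, and that of Ccnd1 without BMP4 replicate 1 or 2 or any 1 control replicate. Tnfrsf11b and Trib3 lost theirs without any 1 BMP4 replicate or control replicate 2 or 3. Acta2 lost its call without replicates 1 or 2 of either group, Fbln1 and Znrf3 without BMP4 replicate 2 or any 1 control replicate, and Pgk1 without any 1 BMP4 replicate or control replicate 2. For Notch1 the arrays were BMP4 replicates 2 and 3 and control replicates 1 and 2, for P4ha3 BMP4 replicates 1 and 2 and control replicates 1 and 3, and for the cartilage factor Sox6 BMP4 replicates 1 and 3 and control replicates 1 and 3. Hspb1 lost its call without any 1 control replicate, Gbp2 without control replicate 1 or 2, Klf5 without control replicate 1, and Tek, the endothelial gene, without BMP4 replicate 3, control replicate 1 or control replicate 3. Id2 is described with the BMP targets. Their log2 changes with all arrays ranged from -0.78 for Gbp2 to 1.03 for Sox6, and 0 of the 106 changed sign under any setting.

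The fit without the intensity trend moved further list counts. Under it 0 osteoblast, 0 skeletal muscle and 0 proteoglycan and matricellular genes rose, against 2, 1 and 4, and 2 growth arrest, 1 Notch, 1 heat shock and 1 antioxidant genes rose, against 4, 2, 2 and 3. It gave 0 lower collagen modification and mature adipocyte genes, and 1 lower gene each in the TGF-beta and YAP, Notch, Wnt response and heat shock lists, with 2 in the antioxidant list. Without the filter on low signals 1 osteoblast, 0 skeletal muscle, 1 Notch and 1 heat shock genes rose, and 1 collagen modification, 0 mature adipocyte, 1 Hedgehog and 1 Wnt response genes fell. Hedgehog also had 1 lower gene with a floor at 1, quantile normalization or a replicate block. With a replicate block 1 osteoblast and 0 skeletal muscle genes rose, and with array weights 2 skeletal muscle genes did. Among the Wnt ligands 0 rose with a floor at 1 or a filter at the 60th percentile. Gpam was not called with quantile normalization, cyclic loess or a replicate block, or without the filter or the trend.

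Besides those named above, other probe sets not past the test belong to Ccnd1, Cdkn1a, Cryab, Fbln1, Gas6, Gli3, Iigp1, Klf5, Mef2c, Pgk1, Stat2, Tgfb1, Tgfb2 and Tpm1. Cdkn1a gave 0.34 (limma adjusted p = 0.11, n = 3) and Cryab 0.31 (adjusted p = 0.333) on them. The lactate dehydrogenase gene Ldha (log2 0.43) was not past the test with median centring (adjusted p = 0.0725) or without the intensity trend (0.0569).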

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

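The tests of array scaling, of single arrays and of other divisions of the samples were chosen before their results were seen; the tests of density, cross-hybridisation, lineage genes, saturation and precision were chosen after.

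Among the 18015 probe sets under the signal filter, which the report does not use, 122 passed the limma test when no filter was applied, 71 higher and 51 lower with BMP4. For 39 of them the gene had no tested probe set. The cartilage gene Cnmd had signals of 2.70 ± 1.13 without and 56.3 ± 11.0 with BMP4 (SD, n = 3; limma adjusted p = 0.00114), and the cytokine Il33 had 41.6 ± 9.91 without and 8.30 ± 7.46 with BMP4 (adjusted p = 0.0344). Both genes were picked after their values were seen, and the lower signal of each lies under the bacterial control signal of 29.1.

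Mitosis and DNA replication genes were higher with BMP4 (median log2 change 0.657 over 46 genes). Array scaling as the whole cause is argued against, since the median was at least 0.563 under quantile, median and cyclic loess normalization. A single deviating array is argued against too, since the median was at least 0.611 whichever array was left out. A difference in density or growth at harvest for reasons other than BMP4 stays open: neither labels nor files give density or culture batch, and the median of the growth arrest genes, 0.066, does not decide it. An effect of BMP4 on proliferation is the biological explanation the design offers, and it may apply but cannot be told apart from such a difference.

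The chondrocyte and mature adipocyte lists were not past camera with an estimated correlation (adjusted p = 0.13 and 0.26). At the preset correlation both shifted upward with BMP4, the latter not with a filter at the 60th percentile (camera adjusted p = 0.175). If single cross-hybridising probe sets were the cause, further probe sets of the called genes would seldom agree, and 5 of 6 (of 4 genes) rose at an unadjusted p under 0.05, the exception being a dim Sox9 probe set; the other called genes have no second kept probe set, so this bears on those 4 genes alone. A rise of all lineage genes alike stays open. The median over the 28 genes of both lists was 0.476 against 0.14 over 47 genes of the other lineage lists, a difference of 0.336, but the lists were compared because these had risen, so the difference decides nothing. A candidate explanation is that BMP4 moves the cultures, or parts of them, toward both lineages; arrays of whole cultures do not show whether the same cells carry both programs.

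Id1, Id3 and Smad7, known targets of BMP signalling, were not past the test. Low precision is argued against for a 2-fold rise, since the highest of the upper 95% limits was a log2 change of 0.275, although smaller changes remain possible. General saturation at these signals is argued against, since 11 probe sets brighter than all 3 genes changed at least 2-fold. For the probes of the 3 genes themselves this test cannot exclude it. This test replaced an earlier one, dropped after its value was seen because it lay close to its bound, which compared the signal of Id3 (1674) with that of the brightest probe set changed at least 2-fold, in Adamts1 (3447). That BMP signalling had ended or adapted by the time of harvest may explain the pattern, and was not tested because there is a single time point.

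The real groups gave 2464 changed probe sets, 321 changed at least 2-fold and 11 lists, and the highest counts among the other divisions of the 6 arrays were 1, 1 and 10. In each case 1 of the 10 divisions, the real one, gave a count as large, and 10 divisions are too few for a share under 0.05. The other divisions also put arrays of both groups on both sides. They kept part of the group difference and added the rest to the spread, so their counts are not rates of false calls.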

How the results depend on the processing

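All settings here were planned before the data were examined. The number of changed probe sets (2464) was 1422 without the intensity trend and between 1622 (without control replicate 2) and 1996 (without BMP4 replicate 1) when 1 array was left out; under the other settings it lay within 1.5 times. The number changed at least 2-fold (321) was 142 with a pseudocount of 64, which shrinks the change of low signals by construction. The number of lists past camera (11) was 0 with an estimated correlation, also for lists whose estimate was below the preset value. Chondrocyte genes were such a list (estimate -0.0313, camera adjusted p = 0.13 against 1.05e-06 at the preset value). A correlation between members above the preset value therefore does not account for that loss. Failing the test with an estimated correlation thus does not by itself show that members of a list are correlated. Apart from the pseudocount the cause was not tested. Of the 106 named genes called, 80 were called under every setting that tested them, 26 lost the call under at least 1, and 0 changed sign; of 14 not called, 4 were called under at least 1 setting. Of 27 genes named outside the rule, after their values were seen, all were called and 7 lost the call under at least 1 setting. The labels do not tie equal replicate numbers to a shared culture, and same-numbered arrays did not deviate together (correlations 0.01, -0.003 and -0.072; the highest of all, 0.079, joined BMP4 replicate 3 and control replicate 2), so the numbers were not taken as pairs. With a replicate block, 2090 probe sets changed, 327 at least 2-fold, and 11 lists passed. Signals near the bacterial controls (up to 29.1) limit what can be said of dim genes.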

Other observations

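The 5 lists below were chosen after the main results were seen; each list's test was set out before its own result was known. Members are named here after their values were seen.

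Of 31 measured genes of amino acid supply and tRNA charging 13 rose and 1 fell, or 18 and 1 adjusted over the list alone. With median centring 7 rose, without the intensity trend 6, and with 1 array left out 9 to 12. Mthfd2, a mitochondrial folate enzyme, went from 146 ± 21.3 to 293 ± 18.1 (SD, n = 3), a log2 change of 0.94 ± 0.11 (SE, limma adjusted p = 0.000261). The serine synthesis enzymes Psat1 and Phgdh rose by 0.65 and 0.52, the amino acid transporter Slc7a5 by 0.62 and the alanyl-tRNA synthetase Aars by 0.49, while the stress-induced Nupr1 changed by -0.54. The list was drawn up because Asns, Chac1 and Trib3 had risen, and it shifted the same way (camera adjusted p = 6.2e-06 over the 5 lists; adjusted p = 0.0838 with an estimated correlation). This is consistent with a wider response of amino acid genes, as a hypothesis found and tested on the same arrays.

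Of 12 measured complement and coagulation genes 4 fell and 2 rose, or 7 and 2 adjusted over the list alone. C1s1 and C1ra, the proteases of the first complement component, changed by -1.38 ± 0.10 and -1.06 ± 0.09 (SE, limma adjusted p = 9.29e-06 and 3.01e-05, n = 3), and their inhibitor Serping1 by -1.02. The thrombin receptor F2r and tissue factor, F3, rose by 0.25 and 0.32. F2r lost its call when any 1 array was left out, and F3 without any array except control replicate 1. Neither was called with median centring, without the filter, without the intensity trend or with a replicate block. The list was drawn up to ask whether such genes moved with Cfb and Thbd, as seen on these arrays. It shifted downward (camera adjusted p = 0.000122, or 0.0643 with an estimated correlation). This too is a hypothesis found and tested on the same arrays.

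The axon guidance list was likewise drawn up from a gene seen on these arrays, Slit3. Axon guidance genes moved in both directions, with 5 of 25 lower, among them Sema5a (log2 -1.23) and Slit2 (-0.73), and 3 higher, among them Unc5b (0.71). The list was not past camera (adjusted p = 0.257, fry adjusted p = 0.00245). Homeobox cluster genes (1 of 12 higher, Hoxa3 at 0.54; adjusted p = 0.195; fry adjusted p = 0.0438) and circadian clock genes (1 of 16 higher and 2 lower; adjusted p = 0.87) were not past it either. Hoxa3 was not called without BMP4 replicate 3 or any of the control replicates, with median centring, or without the intensity trend. Of the clock genes 0 were called higher without BMP4 replicate 2, BMP4 replicate 3, control replicate 2 or control replicate 3. This was also so with median centring or a replicate block, and without the filter or the intensity trend. The number called lower was 1 without BMP4 replicate 1, BMP4 replicate 2, control replicate 2 or the intensity trend, and 0 without control replicate 3. The bound set for these lists, any p over the threshold, was too wide, because a p that misses the threshold does not exclude a shift. Clock genes had a median of 0.04 and a mean of 0.02 with a downward camera direction. That direction turned upward with array weights and without BMP4 replicate 1 or control replicate 1. Fry, which does not compare a list with the other genes, pointed upward.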
